A study of Mus musculus with 12 samples.

How the data were processed

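The γ and δ chains of the T cell receptor were sequenced in bulk from γδ T cells of mice that carry a knocked-in δ chain gene and from mice that do not. Per the labels' protocols, cells positive for CD3 and the γδ receptor and negative for the αβ receptor were sorted from spleen and from the small-intestinal epithelium (small-intestinal intraepithelial lymphocytes, SI-IEL). RNA was copied into cDNA with primers in the constant regions of both chains that carried a random identifier, and amplified with a multiplex of V gene primers that carried a further identifier (molecular amplification fingerprinting), again per the labels' protocols. The design text of the series speaks of single-cell sequencing of spleen cells, whereas the samples analysed here are bulk receptor amplicons of both tissues. The labels name the strain by its knocked-in chain, V6D2J1, and give the genotypes as Tcrd KI/- and Tcrd +/-, so that both genotypes carry 1 usable copy of the δ locus. Mice of the first genotype are called KI and those of the second WT, as in the sample titles.

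The authors deposited 1 annotation table per library in the column format of the AIRR community, per the file headers, with each line holding a consensus of merged read pairs that share a unique molecular identifier (UMI). Per the file headers, the deposited V identity is a percent, namely the share of aligned bases equal to the best-matching germline V gene. The remaining deposited columns used here hold other kinds of values, per the file headers: gene calls, junction sequences, the productive call, the junction length in residues and the number of untemplated bases between V and the next segment (the np1 length). FastQC, without a version, is the tool that the submitters' processing notes name. The annotation tool's version, its germline set, the program that grouped the UMIs, its thresholds and a genome build are not given in the sources used here. No deposited column holds a number of reads or molecules, so weighting by reads was not possible.

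Lines of a library that shared a UMI held identical sequences (0 UMIs with more than 1 sequence), so each distinct UMI was counted once. The 12 tables held 346482 lines and 267643 distinct UMIs, from 10687 to 45847 per library. Of these, 132492 were productive γ chain UMIs, from 3297 to 24364 per library, and all γ chain shares are percentages of them. The bases seen at each position of the identifiers allow 708588 different ones, of which a library used 1.51% to 6.47%. 185 UMIs without a junction were left out. 46 UMIs carried a TRAJ gene, and 0 carried a TRB or immunoglobulin locus. The primers in the γ and δ constant regions do not copy such transcripts, so this number says nothing about αβ T cells or B cells in the sort. A share of 0 in a library allows up to 3 UMIs, which is 0.0123% to 0.091% of productive γ UMIs. Confidence intervals of single libraries are exact Clopper-Pearson intervals at 95%. Floors and intervals cover counting error only, and multiplex V primers can differ in efficiency, so shares were compared between libraries and not read as proportions of cells.

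Samples were grouped by title into 4 groups of 3: spleen KI, spleen WT, SI-IEL KI and SI-IEL WT. For 2 libraries the title and the genotype field of the labels contradict each other. The library titled SI-IEL WT replicate 1 has the genotype field Tcrd KI/-, and the library titled SI-IEL KI replicate 3 has Tcrd +/-. Grouping by title is the main setting, fixed before the data were examined, as were the tests, the lists and most alternatives. Results that involve SI-IEL are also given with the groups of the genotype field. No library was moved because of its values. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these libraries. Counts of clonotypes differed between all pairs of replicates by title by more than sampling noise (chi-square per degree of freedom from 1.64 to 47.6), and so did the further pairs that the genotype field forms (9.09 to 23.4). No library was therefore a plain repeat count of the molecules of another replicate, and each was counted as 1 sample. This does not show that they came from separate mice, and libraries from the same mouse are not excluded.

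A clonotype was defined as V gene, J gene and junction amino acids. Shares, overlaps, diversities and junction features were compared by exact permutation tests, two-sided except for overlap, which was one-sided. Within a tissue, 20 arrangements exist and the smallest possible p is 0.10, so no comparison of 3 against 3 libraries can pass 0.05. Permuting the genotype within each tissue, or the tissue within each genotype, gives 400 arrangements and a smallest p of 0.005. Benjamini-Hochberg adjustment was made over the V genes, over the J genes, over the V-J pairs or over the list of preset junctions. The distance between groups is the total variation distance of their mean V gene shares, in percentage points. Diversity is the Shannon effective number of clonotypes after thinning each library to 3297 UMIs, as a mean of 20 draws. Productive V-J shares expected in spleen KI from amplification alone were those of WT multiplied by the KI to WT ratio of the non-productive shares of each pair, scaled to the same total. Overlap is the Morisita-Horn index, which is 1 for identical clonotype shares and 0 for disjoint ones.

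Single clonotypes were tested with limma on log2(CPM + 10), where CPM is the UMI count scaled by the library's total in the usual way, with all 4 groups in 1 fit. The planned count model was not run. No deposited column holds counts, and limma on this scale had been named beforehand for that case. UMIs were counted here from the deposited lines, so a count model could have been fitted to them. Clonotypes with at least 10 UMIs in at least 3 libraries entered, which left 207, and an adjusted p under 0.05 counted as a call. The added 10 CPM lies below the value of 1 UMI, which is 41.0 to 303.3 CPM, so a clonotype absent from a library adds much spread and fitted changes against absent clonotypes are no bound. For clonotypes absent from every library of a group, the fold is given against the floor of 3 UMIs over that group. The test was tried on simulated data with 4-fold changes. It recovered 25% of changed clonotypes between spleen KI and WT, 42.9% between SI-IEL KI and WT, 89.2% between the tissues and 12.1% for the difference of genotype effects, while 0.7%, 0%, 1.4% and 1.4% of unchanged clonotypes were called. The simulation gave all clonotypes 1 fixed spread between libraries. Some frequent SI-IEL clonotypes spread more by title, such as TRGV7 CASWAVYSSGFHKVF at 11.9% ± 10.6 in KI. Recovery in the real SI-IEL groups by title may therefore be lower.

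By the rule fixed beforehand, the text names each TRGV and TRGJ gene and TRDV family of at least 1% in any group, V-J pairs of at least 5%, the 5 clonotypes with the highest mean share in each group, and per comparison up to 10 called clonotypes with the smallest adjusted p among those whose groups do not overlap. It also names the 5 preset junctions taken from textbook knowledge: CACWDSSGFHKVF with TRGV5 or TRGV6, CSYGxYSSGFHKVF with TRGV4 (x is any residue), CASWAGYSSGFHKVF with TRGV7, CAVWI followed by up to 2 residues and GTSWVKIF with TRGV1 and TRGJ4, and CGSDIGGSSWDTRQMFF with TRDV4. The alternatives tried were the genotype field, both contradictory libraries left out, each replicate left out, a replicate block, lines in place of UMIs, non-productive chains included, single-gene calls, V identity of at least 95%, nucleotide clonotypes, no filter on low counts, only the compared groups in the fit, other diversity measures and, chosen after seeing the data, an intensity trend, voom weights, an added 200 CPM, thinned libraries and the leaving out of V-J pairs across clusters. Gene positions are those of GRCm38 in the GENCODE M21 annotation, matched by sequence; the files name no build. Several δ V genes matched several annotated genes or none, and no position is given for them. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.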

Results

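The γ and δ chain transcripts of sorted γδ T cells were sequenced from 12 libraries, 3 each of spleen KI, spleen WT, SI-IEL KI and SI-IEL WT by title. Per the labels, KI mice carry a rearranged δ chain gene knocked into 1 copy of the δ locus, and WT mice carry 1 unmodified copy. The γ repertoires of the genotypes were compared, without showing that the δ chain of the KI cells was fixed. Productive γ UMIs numbered 14716, 9907 and 9920 in the spleen KI libraries and 3297, 6622 and 5132 in the spleen WT libraries. The libraries titled SI-IEL KI held 14568, 8670 and 24364, and those titled SI-IEL WT held 13384, 9694 and 12218. Values below are means ± SD over 3 libraries unless stated, and percentages of γ chains are shares of productive γ UMIs. In spleen, γ shares rest on fewer UMIs in WT than in KI libraries.

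The mouse γ locus lies on chromosome 13 of GRCm38 as clusters of V and J genes. TRGV7 (19178024 to 19178492), the main V gene of intestinal intraepithelial γδ T cells, TRGV4 (19184974 to 19185506), common in lymphoid organs, TRGV6 (19190356 to 19190929), used by invariant IL-17-producing tissue cells, and TRGV5 (19192278 to 19192725), used by epidermal γδ T cells, share TRGJ1 (19210343 to 19210402). TRGV3 (19242845 to 19243301) lies beside TRGJ3 (19257117 to 19257176), although in spleen more TRGV3 UMIs carried TRGJ4 than TRGJ3. TRGV2 (19336573 to 19337167) rearranges to TRGJ2 (19311245 to 19311304), both on the minus strand. TRGV1 (19339989 to 19340454), the other main V gene of lymphoid γδ T cells, rearranges to TRGJ4 (19342152 to 19342212). The δ genes lie on chromosome 14, among them TRDJ1 (54123138 to 54123188), TRDV4 (54074905 to 54075515), which forms the δ chain of the invariant TRGV5 and TRGV6 cells, and TRDV5 (54148662 to 54149294, minus strand).

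Whether the δ chain separated the genotypes was asked first, because the δ gene is the locus that was changed. Libraries of spleen KI mice held almost no δ chain UMIs, whereas δ chains made up most UMIs of spleen WT libraries. The labels do not say whether the V gene primers amplify the knocked-in transcript. The δ share of γ and δ UMIs was 0.233% ± 0.164 in spleen KI and 72.4% ± 7.07 in spleen WT (two-sided exact permutation p 0.10, the smallest possible for 3 against 3). Among spleen KI libraries it was 0.109% (95% Clopper-Pearson interval 0.0692 to 0.164), 0.418% (0.320 to 0.537) and 0.171% (0.109 to 0.254). In SI-IEL the title did not sort the libraries by δ share, which was 13.3% ± 22.5 for those titled KI and 22.3% ± 19.1 for those titled WT (two-sided exact p 0.90). The library titled SI-IEL KI replicate 3, of genotype field Tcrd +/-, had 39.3% δ UMIs (38.9 to 39.8). The library titled SI-IEL WT replicate 1, of genotype field Tcrd KI/-, had 0.211% (0.146 to 0.294). With the groups of the genotype field the SI-IEL shares were 0.268% ± 0.160 in KI and 35.3% ± 3.55 in WT (two-sided exact p 0.10). Over both tissues, KI minus WT was −40.6 percentage points by title (6.77% against 47.3%, two-sided exact p 0.045) and −53.6 by genotype field (0.250% against 53.9%, two-sided exact p 0.005, the smallest possible).

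**Figure D1:**
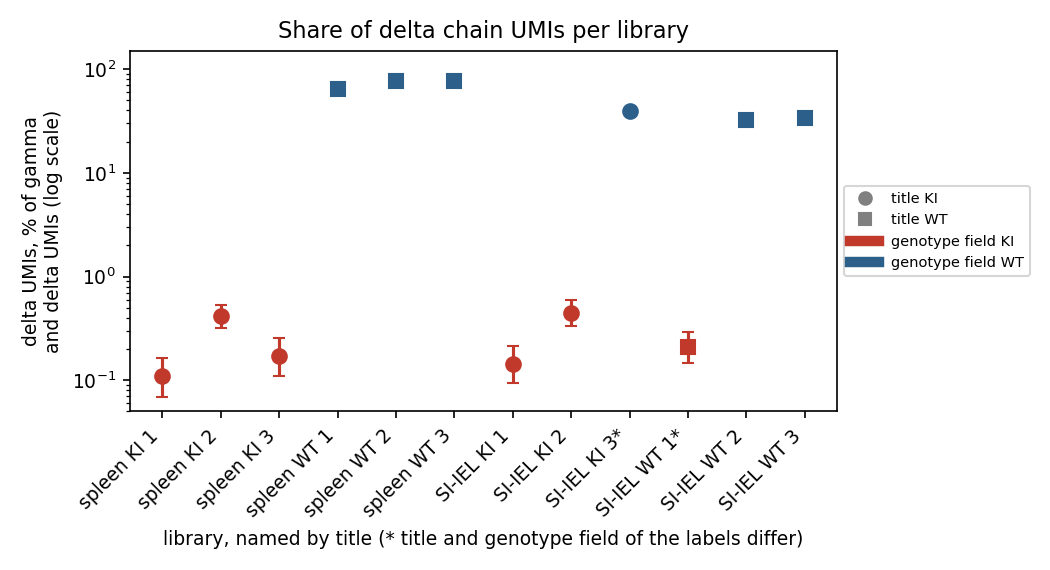
δ chain share of γ and δ UMIs (%, logarithmic axis) in each of the 12 libraries, with exact 95% intervals as bars, colour for the genotype field, marker shape for the title and an asterisk on the 2 libraries whose labels contradict each other. All 6 libraries of genotype field Tcrd KI/- lie at or below 0.449%, and all 6 of Tcrd +/- lie at or above 32.6%.

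The δ chain that was knocked in is named V6D2J1 by the strain label, that is, a chain of a DV6 family V gene and TRDJ1. The 3 spleen KI libraries held 106 productive δ UMIs, of which 51 joined DV6 to TRDJ1. These carried 51 different junctions with at most 1 UMI each, so the rule of taking the most frequent junction named no chain and its share is not given. Lines per UMI also separated the genotypes in spleen, at 1.03 ± 0.0091 in KI against 1.36 ± 0.153 in WT (two-sided exact p 0.10). In SI-IEL they were 1.21 ± 0.314 against 1.40 ± 0.345 by title (two-sided exact p 0.70) and 1.03 ± 0.0031 against 1.59 ± 0.107 by genotype field (two-sided exact p 0.10). Over both tissues the two-sided exact p was 0.095 by title and 0.005 by genotype field.

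In spleen, TRGV1 was the most used γ V gene in both genotypes and took a larger share in KI mice. TRGV7, the intestinal V gene, TRGV3 and TRGV5 took smaller shares there. TRGV4 and TRGV2 did not separate the genotypes. The J genes followed, with TRGJ4, the partner of TRGV1, more used in KI. TRGV1 made up 54.4% ± 1.19 in spleen KI and 40.7% ± 3.40 in spleen WT, and TRGV1 with TRGJ4 52.6% ± 2.01 and 40.5% ± 3.45. TRGV7 made up 4.39% ± 0.415 and 6.99% ± 2.92, of which TRGV7 with TRGJ1 were 3.65% ± 0.350 and 6.67% ± 2.88. Among non-productive γ UMIs TRGV7 with TRGJ1 also had a lower mean, at 1.12% ± 0.0702 in spleen KI and 1.82% ± 0.823 in spleen WT (two-sided exact p 0.40). TRGV3 was at 1.87% ± 0.247 against 3.28% ± 0.388, and TRGV5 at 0.289% against 0.492%. TRGV4 was at 19.6% ± 2.93 against 25.1% ± 4.16 (TRGV4 with TRGJ1 19.3% ± 2.95 against 24.9% ± 4.18). TRGV2 was at 18.4% ± 2.78 against 21.7% ± 2.17, and TRGV6 at 1.03% ± 0.366 against 1.79% ± 1.501. TRGJ4 was at 58.7% ± 0.683 against 42.8% ± 3.98, TRGJ1 at 24.4% ± 2.84 against 33.9% ± 5.82, TRGJ2 at 16.3% ± 2.23 against 21.9% ± 2.14 and TRGJ3 at 0.649% against 1.39%. Libraries of the genotypes did not overlap for TRGV1, TRGV3, TRGV5, TRGV7, TRGJ2, TRGJ3 and TRGJ4 (two-sided exact p 0.10 each, adjusted 0.175 over V genes and 0.133 over J genes). TRGV4 (p 0.20), TRGV2 (p 0.30) and TRGV6 (p 0.70) overlapped by the same exact test. The distance between the mean V gene profiles was 13.7 percentage points (two-sided exact p 0.10).

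TRGV1 with TRGJ2 and TRGV2 with TRGJ4, pairs across neighbouring clusters, were far more frequent in spleen KI than in spleen WT libraries. Their joint share was 5.64% ± 3.21 against 0.292% ± 0.0452 (two-sided exact p 0.10). TRGV2 with TRGJ2, the usual pair, made up 14.4% ± 2.18 against 21.5% ± 2.11 (two-sided exact p 0.10), and it was also lower among non-productive γ UMIs, at 39.8% ± 5.15 against 52.4% ± 3.70 (two-sided exact p 0.10). Of the TRGV2 with TRGJ4 UMIs that could be read in libraries of genotype field Tcrd KI/-, 57.0% (805 of 1413) matched TRGV2 in the first part of the V segment and TRGV1 in the last part. In libraries of Tcrd +/- 0 of 11 did. Of the TRGV1 with TRGJ2 UMIs read in libraries of Tcrd KI/-, 58.7% (437 of 744) matched TRGV1 in the first part and TRGV2 in the last part. In libraries of Tcrd +/- 0 of 45 did so. TRGV3 with TRGJ4, also a pair across clusters, went the other way in spleen, at 1.34% ± 0.213 in KI and 1.96% ± 0.469 in WT without overlap (two-sided exact p 0.10). From 51.2% to 75.2% of its UMIs in the spleen libraries carried a junction also found with TRGV1 and TRGJ4. Whether molecules of this pair were chimeric was not tested. TRGV3 with TRGJ3 was at 0.470% ± 0.145 and 1.32% ± 0.361 (two-sided exact p 0.10).

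**Figure D2:**
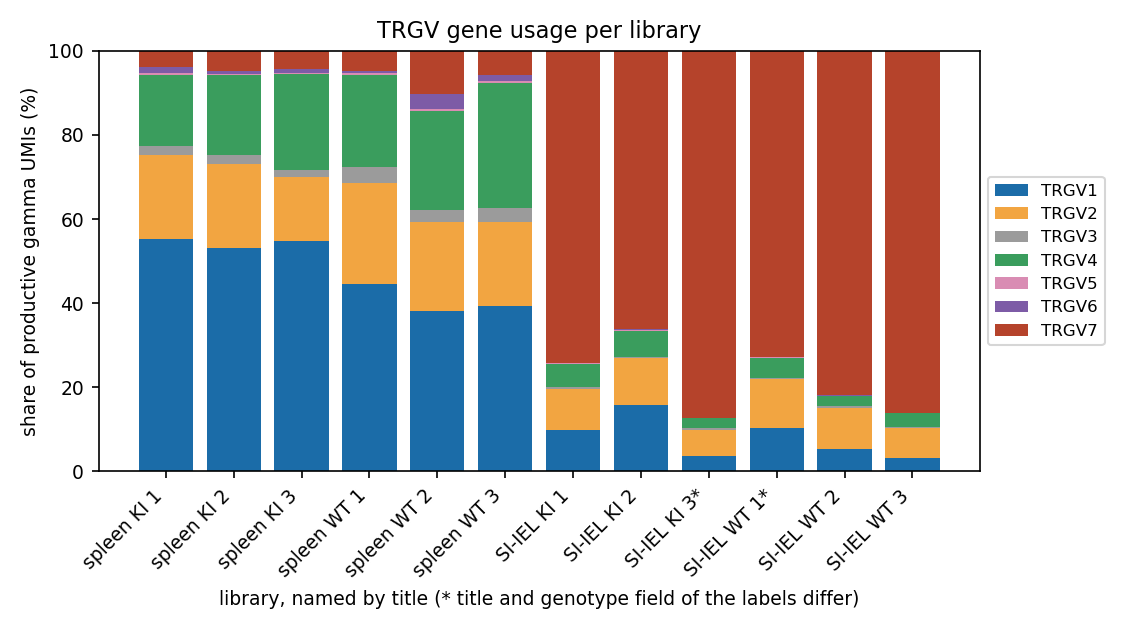
Stacked bars of the shares of TRGV1 to TRGV7 (% of productive γ UMIs) in each of the 12 libraries. TRGV1 takes the largest share in the spleen libraries, with group means of 54.4% in KI and 40.7% in WT, and TRGV7 takes most of each SI-IEL library.

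Junctions known from lymphoid and tissue γδ T cells were examined as a preset list. The TRGV1 to TRGJ4 junctions starting CAVWI, a frequent family of lymphoid cells, made up more of the spleen KI repertoire. The TRGV4 family CSYGxYSSGFHKVF, the TRGV7 junction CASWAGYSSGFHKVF and the invariant TRGV6 junction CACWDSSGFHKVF made up less. These are shares of all productive γ UMIs, so differences in V gene share enter them. Shares within a V gene were not tested, so the CAVWI and TRGV4 families may largely restate the shares of TRGV1 and TRGV4. The CAVWI family was at 18.8% ± 0.878 in spleen KI and 13.1% ± 1.10 in spleen WT, and the TRGV4 family at 7.09% ± 1.26 and 10.0003% ± 0.642. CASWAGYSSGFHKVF was at 0.248% ± 0.0269 and 0.901% ± 0.416. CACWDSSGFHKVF with TRGV6 was at 0.0495% ± 0.0102 in spleen KI and 1.09% ± 1.07 in spleen WT, where the libraries ranged from 0.182% to 2.27%. In these 4 junction groups the genotypes did not overlap (two-sided exact p 0.10 each, 0.12 adjusted over the list alone). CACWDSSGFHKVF with TRGV5 overlapped, at 0.0371% ± 0.0154 against 0.124% ± 0.0751 (two-sided exact p 0.30). TRDV4 with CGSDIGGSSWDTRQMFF, the invariant δ chain that pairs with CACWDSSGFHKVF, had 17, 85 and 113 UMIs in the spleen WT libraries. Spleen KI libraries had 2, 2 and 0 among only 23, 60 and 23 productive δ UMIs, so these counts show no lower share of δ chains.

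Untemplated bases set how far a γ junction departs from germline, and in spleen the share of junctions without them separated the genotypes for TRGV1 and TRGV6. TRGV6 junctions without untemplated bases made up 9.51% ± 4.40 of TRGV6 UMIs in KI and 62.1% ± 13.0 in WT. Among TRGV1 junctions 5.42% ± 0.282 in KI and 12.6% ± 1.02 in WT had none, and the mean number of such bases was 3.89 ± 0.0342 against 3.28 ± 0.114 (for TRGV6 3.47 ± 0.462 against 1.46 ± 0.725). TRGV1 junctions averaged 14.6 ± 0.0137 residues in KI and 14.3 ± 0.0596 in WT, and TRGV6 junctions 14.1 ± 0.112 and 13.4 ± 0.282. Junctions were shorter in KI for TRGV7, at 14.3 ± 0.0950 and 14.6 ± 0.0456, and for TRGV4, at 13.48 ± 0.0163 and 13.68 ± 0.0679. TRGV7 junctions went the other way in untemplated bases, at 3.41 ± 0.114 in KI against 3.60 ± 0.0485 in WT. Each of these had a two-sided exact p of 0.10 (adjusted 0.15 to 0.3). Junctions without untemplated bases overlapped between the genotypes for the other V genes, at 24.0% against 19.6% for TRGV4 (two-sided exact p 0.20), 12.9% against 9.25% for TRGV3 (p 0.50), 5.78% against 4.35% for TRGV7 (p 0.40) and 6.81% against 7.44% for TRGV2 (p 0.30). Over both tissues by genotype field, TRGV7 junctions were shorter in KI than in WT (14.4 against 14.7 residues, two-sided exact p 0.005, adjusted 0.03), whereas by title the adjusted exact p was 0.06.

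**Figure D3:**
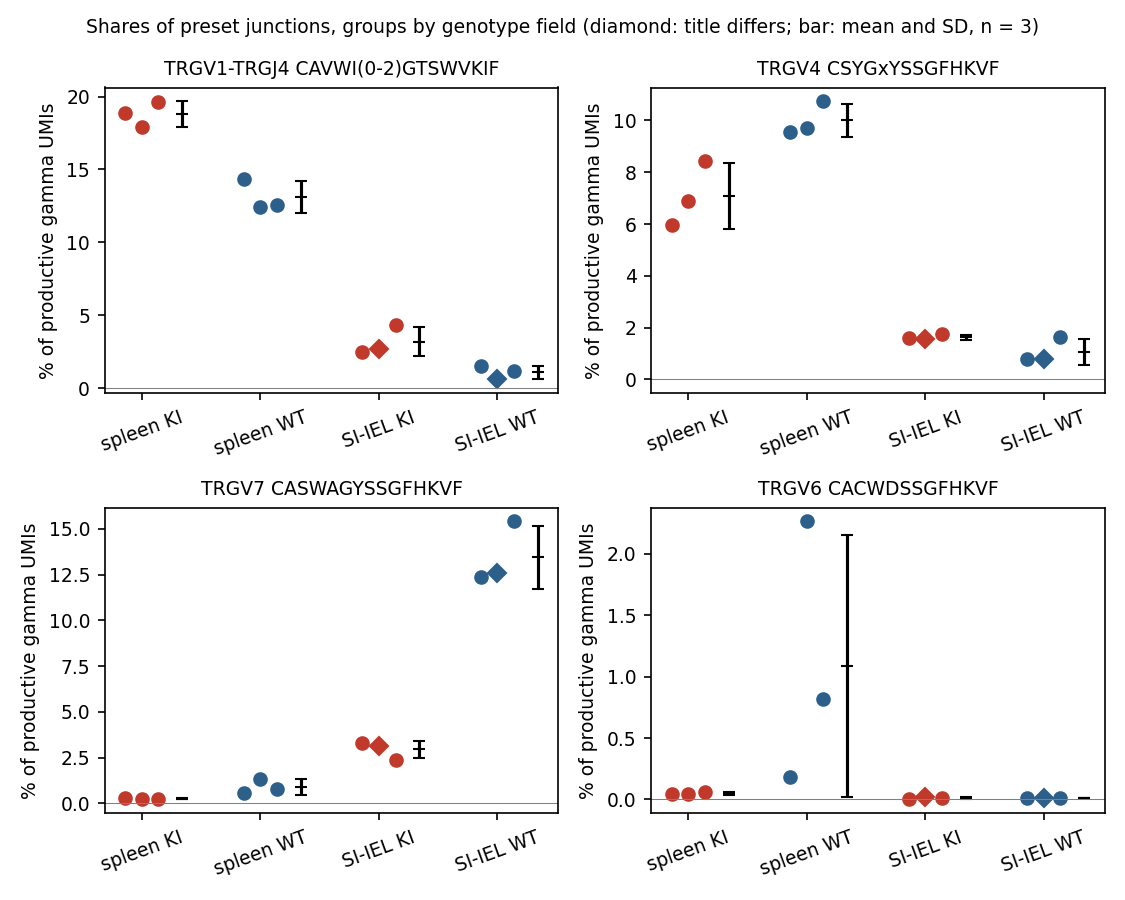
Share of productive γ UMIs (%) of 4 preset junction groups in each library, with points for libraries, diamonds for the 2 libraries whose title differs from the genotype field by which they are placed, and bars for the mean ± SD of 3 libraries. The CAVWI family lies at 18.8% in spleen KI against 13.1% in spleen WT, and TRGV7 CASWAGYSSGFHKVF at 2.95% in SI-IEL KI against 13.4% in SI-IEL WT by genotype field.

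Single γ clonotypes ask whether the same junctions dominate in KI and WT spleens. The most frequent clonotype of both was TRGV1 to TRGJ4 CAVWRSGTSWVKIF. Of the clonotypes called by title, those higher in KI carried TRGV1 or TRGV2 with TRGJ4, and the one lower carried TRGV7. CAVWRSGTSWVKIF was at 6.40% ± 0.382 in KI and 3.32% ± 0.549 in WT (log2 change 0.96, SE 0.85, limma adjusted p 0.711). Of the further TRGV1 to TRGJ4 clonotypes among the 5 most frequent, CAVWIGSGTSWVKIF was at 2.72% ± 0.156 in KI and 0.378% ± 0.0467 in WT (limma adjusted p 0.0981). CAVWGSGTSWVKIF was at 0.765% ± 0.163 and 2.35% ± 0.314 (limma adjusted p 0.381). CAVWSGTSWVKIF reached 2.25% ± 0.481 in WT (limma adjusted p 0.280), and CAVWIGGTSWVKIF 1.59% ± 0.0863 in KI (limma adjusted p 0.952). The TRGV4 clonotypes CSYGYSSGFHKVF, at 2.76% ± 0.818 and 2.26% ± 0.842, and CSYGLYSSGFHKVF, at 1.65% ± 0.155 and 2.32% ± 0.177, were not called (limma adjusted p 0.880 and 0.797). By limma, 3 of 207 tested clonotypes passed, 2 higher and 1 lower in KI, with 28 at an unadjusted p under 0.05. The genotypes did not overlap for 94 of the 207 (45.4%, against 10% for random labels). A clonotype could enter through the 3 libraries of 1 group alone, more easily in the deeper KI libraries, so 10% is no strict yardstick here. TRGV2 to TRGJ4 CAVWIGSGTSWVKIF, of a pair across clusters and with the junction of a frequent TRGV1 clonotype, had 64 UMIs in KI and 0 in WT (at least 9.30-fold higher, limma adjusted p 5.292e-05). TRGV1 to TRGJ4 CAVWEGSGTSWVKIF had 61 and 1 (log2 change 6.04, SE 1.26, limma adjusted p 0.0422), a call that ended without spleen WT 1 or spleen WT 2 (limma adjusted p up to 0.1432). TRGV7 to TRGJ1 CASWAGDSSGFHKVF had 0 UMIs in KI and 11 in WT (at least 8.42-fold higher in WT, limma adjusted p 0.0001744). The number of calls was 0 with nucleotide clonotypes and 1 without any of the 3 spleen KI libraries in turn, where the clonotypes higher in KI no longer had enough UMIs to be tested. The shared fit takes its spread from all 4 groups, among them the SI-IEL groups by title with both contradictory libraries. Its p-values thus do not measure the spread of the spleen libraries alone, and 3 calls do not show that few spleen clonotypes differ. More clonotypes were called with only the spleen groups in the fit. With the SI-IEL libraries grouped by genotype field in the shared fit, 13 were called in spleen, 8 higher and 5 lower in KI.

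Among those 13 calls, TRGV2 to TRGJ4 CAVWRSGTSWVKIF, of the same pair across clusters and with the junction of the most frequent TRGV1 clonotype, was at 0.501% ± 0.307 in KI and 0.0065% in WT (log2 change 7.35, SE 1.08, limma adjusted p 0.00266). TRGV1 to TRGJ4 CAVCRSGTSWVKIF was at 0.334% ± 0.0083 and 0.0613% (log2 change 2.54, SE 0.44, limma adjusted p 0.00831). TRGV7 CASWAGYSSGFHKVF fell by a log2 of 1.79 in KI (SE 0.43, limma adjusted p 0.0384). TRGV7 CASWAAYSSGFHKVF and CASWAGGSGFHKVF and TRGV1 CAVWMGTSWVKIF were also lower (log2 changes −2.45, −2.07 and −2.40 by limma), and TRGV1 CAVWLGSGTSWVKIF was higher (5.93).

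In the small-intestinal epithelium TRGV7 made up most γ chains of every library, as is typical of this site. Grouped by title, the libraries of the genotypes overlapped for every V and J gene. Grouped by genotype field, every KI library used less TRGV7 and more TRGV1, TRGV2 and TRGV4 than every WT library. By title, TRGV7 was at 75.9% ± 10.7 in KI and 80.3% ± 6.76 in WT (two-sided exact p 0.70), TRGV1 at 9.76% ± 6.14 and 6.32% ± 3.71 (p 0.60), TRGV2 at 9.07% ± 2.49 and 9.49% ± 2.14 (p 0.80) and TRGV4 at 4.64% ± 1.99 and 3.50% ± 1.10 (p 0.50). The smallest p possible is 0.10 here too, and the distance between the V gene profiles was 4.80 points (two-sided exact p 0.70). By genotype field, TRGV7 was at 71.0% ± 4.29 in KI and 85.1% ± 2.80 in WT, TRGV1 at 12.02% ± 3.36 and 4.06% ± 1.22, TRGV2 at 10.8% ± 0.872 and 7.76% ± 1.78, and TRGV4 at 5.42% ± 0.682 and 2.72% ± 0.474 (two-sided exact p 0.10 each, adjusted 0.14). TRGJ4 was then at 13.3% ± 2.93 against 4.30% ± 1.38 and TRGJ1 at 76.3% ± 3.64 against 87.6% ± 3.07 (two-sided exact p 0.10 each). TRGV1 with TRGJ4 was at 11.4% ± 3.75 against 4.04% ± 1.21, and TRGV7 with TRGJ1 at 70.5% ± 4.15 against 84.8% ± 2.99 (two-sided exact p 0.10 each). The distance was 14.0 points (two-sided exact p 0.10). TRGV1 with TRGJ2 and TRGV2 with TRGJ4 together made up 1.89% ± 1.17 against 0.0308% ± 0.0102 by genotype field and 1.00% against 0.923% by title (two-sided exact p 0.10 and 1.0).

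The most frequent intestinal γ clonotypes joined TRGV7 to TRGJ1. By title none was called between the genotypes. By genotype field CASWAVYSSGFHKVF was the most frequent in KI and the preset junction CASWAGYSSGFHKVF the most frequent in WT. By title, limma called 0 of 207 clonotypes, with 12 at an unadjusted p under 0.05, and limma with voom weights also called 0. Groups did not overlap for 10 of them (4.8%, against 10% by chance). The most frequent by title were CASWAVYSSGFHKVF at 11.9% ± 10.6 in KI and 8.10% ± 11.01 in WT, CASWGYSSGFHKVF at 7.33% and 6.26%, and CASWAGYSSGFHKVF at 6.08% and 10.3%. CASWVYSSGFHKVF was at 4.88% and 2.71%, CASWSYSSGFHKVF at 6.15% in KI, and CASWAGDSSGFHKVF at 1.54% and 3.08%. By genotype field, limma called 76 clonotypes, 54 higher and 22 lower in KI and groups did not overlap for 103 (49.8%, against 10% for random labels). Clonotypes could enter through the libraries of 1 group alone here too, so 10% is no strict yardstick. Of the 54 calls higher in KI 39 carried TRGV1 (of 75 tested), 7 TRGV7, 5 TRGV4 and 3 TRGV2. All 22 lower ones carried TRGV7 (of 77 tested). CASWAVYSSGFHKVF rose to 17.7% ± 7.95 in KI from 2.23% ± 0.861 in WT (log2 change 2.93, SE 0.66, limma adjusted p 0.00658, but 0.09375 with thinned libraries), and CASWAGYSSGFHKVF was at 2.95% ± 0.484 against 13.4% ± 1.71 (log2 change −2.19, SE 0.43, limma adjusted p 0.00301). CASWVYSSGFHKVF was higher in KI (log2 change 1.57, limma adjusted p 0.0387), a call that ended without SI-IEL KI 1, without SI-IEL KI 2 or without SI-IEL KI 3 (limma adjusted p up to 0.1369), while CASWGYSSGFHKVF (limma adjusted p 0.109), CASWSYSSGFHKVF (0.0708), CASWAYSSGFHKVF (0.438) and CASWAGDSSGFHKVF (0.988) were not called.

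Among the 76 calls with the smallest adjusted p by genotype field, TRGV7 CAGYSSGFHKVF had 67 UMIs in KI and 0 in WT (at least 28.2-fold higher, limma adjusted p 9.307e-08). TRGV7 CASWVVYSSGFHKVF was at 0.560% ± 0.199 against 0.0014%. TRGV1 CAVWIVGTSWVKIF, TRGV1 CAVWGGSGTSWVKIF and TRGV4 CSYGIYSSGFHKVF were absent from WT and at least 7.16-fold, 4.21-fold and 3.37-fold higher in KI. Lower in KI were TRGV7 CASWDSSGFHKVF at 0.0396% ± 0.0202 against 1.20% ± 0.408 (log2 change −4.95, SE 0.55, limma adjusted p 8.836e-05) and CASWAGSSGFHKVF at 0.184% against 2.32% ± 1.06 (log2 change −3.88). TRGV7 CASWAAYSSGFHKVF, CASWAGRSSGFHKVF and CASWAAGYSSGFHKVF also fell by limma (log2 changes −4.24, −3.67 and −5.83).

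Taking spleen and gut jointly asks whether the genotypes differ in the same γ genes at both sites. TRGV1 and TRGJ4 were higher in KI under both groupings, and only the genotype field gave adjusted p-values under 0.05. TRGV7, TRGJ1 and TRGJ3 were lower in KI by genotype field. No other V or J gene passed a test. The distance between KI and WT profiles was 8.58 points by title (two-sided exact p 0.055) and 10.8 points by genotype field (two-sided exact p 0.005). TRGV1 averaged 33.2% in KI and 22.4% in WT by genotype field (two-sided exact p 0.005, adjusted 0.0175) and 32.1% and 23.5% by title (p 0.03, adjusted 0.21). TRGV7 averaged 37.7% and 46.0% by genotype field (two-sided exact p 0.005, adjusted 0.0175), and 40.1% and 43.6% by title (p 0.33). TRGJ4 averaged 36.0% and 23.6% (two-sided exact p 0.005, adjusted 0.02), TRGJ1 50.4% and 60.8% (p 0.01, adjusted 0.02) and TRGV1 with TRGJ4 32.0% and 22.2% (p 0.005, adjusted 0.009) by genotype field. TRGJ3 averaged 0.439% and 0.840% by genotype field (two-sided exact p 0.025, adjusted 0.0333) and 0.451% and 0.827% by title (p 0.05, adjusted 0.0867), and in SI-IEL alone the genotypes overlapped for it. TRGV2 (14.6% and 14.7%, two-sided exact p 0.955) and TRGV4 (12.5% and 13.9%, p 0.535) overlapped. The CAVWI family averaged 10.99% and 7.10%, and TRGV7 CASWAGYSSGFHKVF 1.60% and 7.17% (two-sided exact p 0.005 each, 0.015 adjusted over the list alone). By title these adjusted exact p-values were 0.07 and 0.162. Both are shares of all productive γ UMIs, so the TRGV1 and TRGV7 differences enter them, and shares within a V gene were not tested. Libraries of genotype field Tcrd KI/- also differed in their δ share, lines per UMI and pairs across clusters, so none of these γ differences was free of them.

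Spleen and intestinal epithelium are known to hold different γδ T cells, and here every γ V and J gene separated them. TRGV7 and TRGJ1 were the genes higher in SI-IEL, and TRGV1, TRGV2, TRGV3, TRGV4, TRGV5 and TRGV6 were higher in spleen. TRGV7 averaged 5.69% in spleen and 78.1% in SI-IEL, TRGV1 47.6% and 8.04%, TRGV4 22.3% and 4.07%, TRGV2 20.1% and 9.28%, TRGV3 2.57% and 0.331%, TRGV6 1.41% and 0.120% and TRGV5 0.391% and 0.0984%. TRGJ1 averaged 29.2% and 82.0%, TRGJ2 19.1% and 8.98%, TRGJ3 1.02% and 0.259% and TRGJ4 50.7% and 8.78%. Each of these 11 genes had a two-sided exact p of 0.005, adjusted 0.005, with no overlap between the 6 libraries of each tissue, under both groupings. TRGV1 with TRGJ4 averaged 46.5% and 7.73%, TRGV7 with TRGJ1 5.16% and 77.7%, TRGV4 with TRGJ1 22.1% and 4.04% and TRGV2 with TRGJ2 18.0% and 8.56%. The distance between the tissues was 72.4 points (two-sided exact p 0.005). Of the preset junctions, the CAVWI family (15.9% against 2.14%), the TRGV4 family (8.54% against 1.35%) and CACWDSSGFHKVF with TRGV6 (0.569% against 0.0101%) were higher in spleen. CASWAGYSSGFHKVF with TRGV7 (0.574% against 8.19%) was higher in SI-IEL (two-sided exact p 0.005 each, 0.005 adjusted over the list alone).

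By limma, 171 of 207 clonotypes differed between the tissues by title, 106 higher and 65 lower in spleen, and 195 by genotype field, 120 higher and 75 lower. By title, 69 of 75 TRGV1, 18 of 22 TRGV4, 16 of 30 TRGV2 and both TRGV3 clonotypes were higher in spleen, and 65 of 77 TRGV7 clonotypes were lower. Tissues did not overlap for 102 of the 207 (49.3%). Higher in spleen by limma were TRGV1 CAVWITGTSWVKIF (log2 change 3.82, SE 0.42), TRGV1 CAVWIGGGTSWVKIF (6.01, SE 0.60), TRGV1 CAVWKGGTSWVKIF (5.50), TRGV4 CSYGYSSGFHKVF (3.56, SE 0.41) and TRGV3 to TRGJ4 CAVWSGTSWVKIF (6.28). TRGV7 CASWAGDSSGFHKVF was lower in spleen (log2 change −7.82, SE 0.47, limma adjusted p 5.574e-07). TRGV7 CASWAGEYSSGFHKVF, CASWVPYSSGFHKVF, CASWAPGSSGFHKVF and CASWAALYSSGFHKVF had 0 UMIs in spleen and fitted log2 changes from −6.94 to −6.28, which are no bound.

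Whether the genotype difference itself depended on the tissue was tested as the spleen difference minus the SI-IEL difference. The exact permutations exchange genotypes within each tissue. They therefore test against no genotype difference in either tissue, not against equal differences in both. TRGV4, TRGV5 and TRGJ2 passed this test by genotype field, with lower means in spleen KI and higher means in SI-IEL KI. Passing it does not show that the genotype difference depended on the tissue. Within a tissue, TRGV4 in spleen and TRGJ2 in SI-IEL overlapped between the genotypes. TRGV5 shares in SI-IEL WT by genotype field, at 0.0082% to 0.0246%, lay near the floor of 3 UMIs. TRGV7 and TRGV1 did not pass. By genotype field TRGV4 was 5.51 points lower in spleen KI and 2.70 higher in SI-IEL KI, a difference of −8.21 (two-sided exact permutation p 0.01, adjusted 0.035). TRGV5 gave −0.364 points (two-sided exact p 0.005, adjusted 0.035), TRGJ2 −7.97 (p 0.01, adjusted 0.04), TRGV2 −6.29 (p 0.025, adjusted 0.0525) and TRGV7 11.4 (p 0.105). By title no V gene had an adjusted p under 0.05, with TRGV4 at −6.65 points (two-sided exact p 0.07, adjusted 0.163) and TRGV3 at −1.49 (p 0.01, adjusted 0.07). By limma 2 clonotypes differed by title, 1 in each direction, with 18 at an unadjusted p under 0.05, and 42 by genotype field, 11 and 31, with 76. Of those by title, TRGV2 to TRGJ4 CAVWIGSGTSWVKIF had 0 UMIs in every SI-IEL library, so its call restates the spleen difference, and TRGV7 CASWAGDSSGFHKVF was present in both tissues but lost its call in 5 of 12 fits with 1 library left out (limma adjusted p up to 0.1048). By genotype field, 4 of the 42 were absent from all libraries of 1 tissue.

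By the Shannon number γ repertoires were about as diverse in KI as in WT mice in spleen, but by the inverse Simpson number they were less diverse in KI. They were far less diverse in SI-IEL, and more alike within than between genotypes in spleen. The effective number of clonotypes was 476 ± 41.7 in spleen KI and 473 ± 30.002 in spleen WT (log2 change 0.01, two-sided exact p 0.90). In SI-IEL it was 106 ± 16.5 and 128 ± 30.4 by title (log2 change −0.25, two-sided exact p 0.40) and 99.5 ± 16.0 and 135 ± 19.1 by genotype field (log2 change −0.44, p 0.20). Spleen exceeded SI-IEL by a log2 of 2.04 (two-sided exact p 0.005). The inverse Simpson number, which weighs frequent clonotypes, was 116 ± 9.67 in spleen KI and 159 ± 14.7 in spleen WT, and the direction in spleen was then reversed. Its libraries did not overlap, at 108 to 127 in spleen KI and 149 to 176 in spleen WT. Without pairs across clusters the Shannon number did not overlap either, at 401 to 438 in spleen KI and 444 to 499 in spleen WT. Overlap in spleen averaged 0.975 within KI, 0.905 within WT and 0.756 between them (difference 0.184, one-sided exact p 0.10). In SI-IEL by title it was 0.489, 0.519 and 0.561 (difference −0.0570, one-sided exact p 0.50), so libraries of the same title were no more alike than those of different titles. By genotype field it was 0.756, 0.900 and 0.346 (difference 0.482, one-sided exact p 0.10). Within KI by genotype field, the libraries titled SI-IEL KI replicate 1 and SI-IEL WT replicate 1 overlapped at 0.974. Their overlaps with SI-IEL KI replicate 2 were 0.666 and 0.627. The labels do not say whether they came from separate mice, so this group may hold fewer than 3 independent repertoires.

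**Figure D4:**
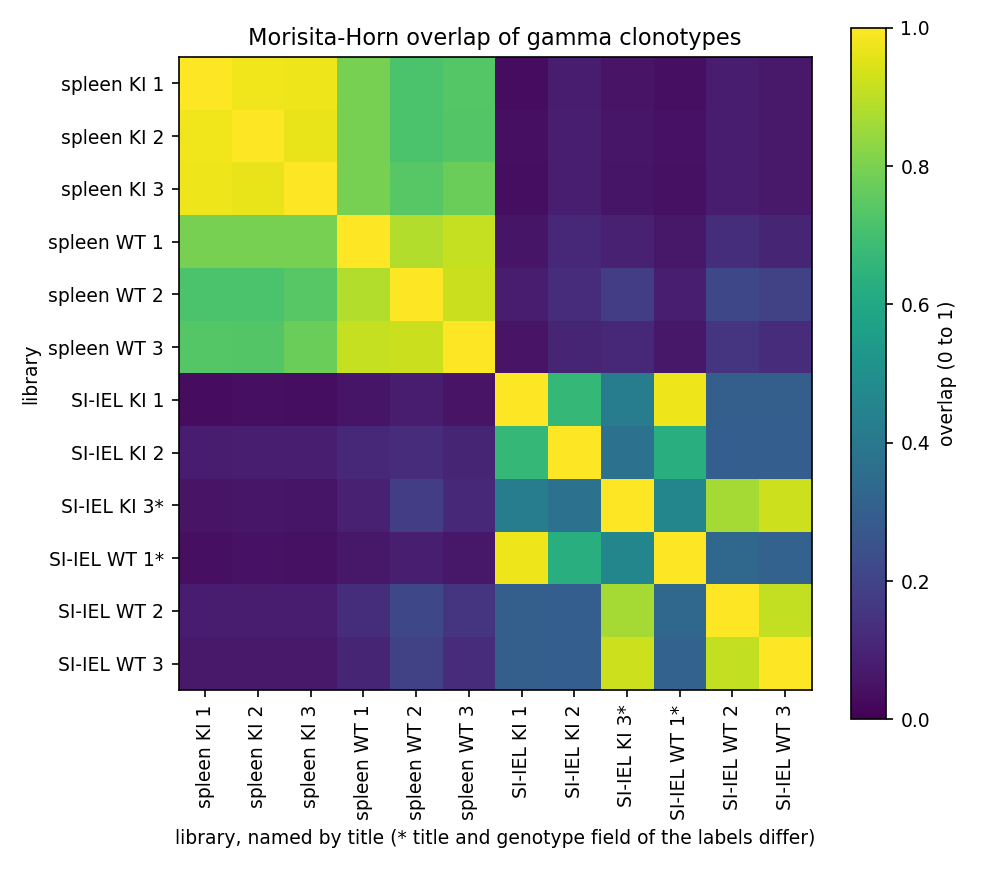
Heat map of the Morisita-Horn overlap of γ clonotypes (0 to 1, no unit) between all pairs of the 12 libraries, ordered by tissue and title. Spleen and SI-IEL libraries overlap little, and the libraries titled SI-IEL KI replicate 1 and SI-IEL WT replicate 1 reach 0.974.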

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

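The exchange of titles, the sharing of identifiers with junctions and the makeup of TRGV2 with TRGJ4 molecules were tested only after those results had been seen, as were the non-productive TRGV2 with TRGJ2 share, the productive shares predicted from all non-productive pairs and the share of matched junctions among the δ UMIs without a shared identifier. The makeup of TRGV1 with TRGJ2 molecules was also read only then.

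In 2 SI-IEL libraries the δ share went against the title and with the genotype field. The library titled WT replicate 1 had 0.211% δ UMIs and the library titled KI replicate 3 had 39.3%. The γ repertoires, which the δ share does not enter, were compared with the other SI-IEL libraries. Overlap was higher with the genotype field's libraries than with the title's by 0.476 for the first library and 0.494 for the second, where a negative difference in either would have spoken against an exchange. Lines per UMI also went with the genotype field, at 1.02 in the first library and 1.57 in the second. So did TRGV2 with TRGJ4, which had 253 UMIs in the first library and 0 in the second. These values argue against the titles as the genotype of these 2 libraries, so SI-IEL groups by title may mix genotypes. An exchange of their titles may be the source of the conflict, and a different genotype of the mice was not tested beyond this.

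Libraries of genotype field Tcrd KI/- held a few δ UMIs of many different junctions, each above the 3 UMIs that a count of 0 allows. They numbered 23, 61 and 24 in spleen KI replicates 1, 2 and 3, 25 and 48 in SI-IEL KI replicates 1 and 2, and 34 in the library titled SI-IEL WT replicate 1. Of these 215 UMIs, 49 shared both identifier and junction with a library of Tcrd +/-, against 0.00616 expected at random. Carry-over between libraries may be the source of that part. In the same order of libraries they numbered 2, 19, 2, 3, 16 and 7, so most lay in spleen KI 2 and SI-IEL KI 2. Junctions also found in a δ-rich library made up 20% to 63.9% of all δ UMIs per library, above the 4.46% to 9.07% among δ-rich libraries, with 37 of 61 in spleen KI 2 found in spleen WT 2, and among the other 166 UMIs 43 (25.9%) matched. For the δ UMIs without a match, carry-over and natural rearrangement of δ genes in the KI mice cannot be told apart, and the latter was not tested.

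Among γ chains set against amplification that differs between libraries rich and poor in δ templates, TRGV1 with TRGJ4 was 12.2 points higher in spleen KI among productive chains but 2.01 points higher among non-productive ones (pairs of libraries from −0.615 to 3.82), and in every pair it exceeded by 7.39 to 12.7 points what the non-productive shares predict, which argues against amplification as the whole cause. TRGV2 with TRGJ2 was lower in spleen KI among productive chains (−7.20 points) and more so among non-productive ones (−12.66, pairs from −20.3 to −4.26), so amplification may be the source of that fall. TRGV7 with TRGJ1 changed by −3.02 points in spleen KI, where the non-productive shares predict −2.62. Observed minus predicted ran from −1.89 to 1.67 over the pairs of libraries, so amplification may be the source of that fall too. TRGV7 was 14.0 points lower in SI-IEL KI by genotype field among productive chains and 4.45 points lower (−4.45, pairs from −7.22 to 0.268) among non-productive ones, so amplification and genotype cannot be told apart there, since a part moved the same way. TRGV2 with TRGJ4, which includes the called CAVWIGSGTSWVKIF and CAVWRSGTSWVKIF, may largely be chimeric molecules formed during amplification, since 57.0% joined a TRGV2 start to a TRGV1 end against 0.452% of TRGV2 with TRGJ2. The same may hold for TRGV1 with TRGJ2, where 58.7% joined a TRGV1 start to a TRGV2 end against 0.344% of TRGV1 with TRGJ4. TRGV4 with TRGJ1 had a lower mean in spleen KI (−5.57 points, with overlap), whereas the non-productive shares predict 3.03 points. Every pair of libraries lay below its prediction (observed minus predicted −13.8 to −4.09). This argues against amplification as the source of that lower mean. Among non-productive chains the pair was 5.77 points higher in spleen KI (pairs of libraries from −2.28 to 13.9). A selection of γ chains by the knocked-in δ chain, the biological explanation that the design names, was not tested. It remains open for TRGV1, TRGV2, TRGV4 and TRGV7. Amplification is open too for TRGV2, TRGV7 and the other genes and junctions, and for TRGV1 as a part of the cause.

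For some γ clonotypes and genes the spleen difference between genotypes minus the SI-IEL difference passed its test. By title, limma called 2 clonotypes, TRGV2 to TRGJ4 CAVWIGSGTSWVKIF with a log2 difference of 7.31 and TRGV7 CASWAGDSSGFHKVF with −5.19. By genotype field it called 42. Those named that were relatively higher in spleen KI were TRGV2 to TRGJ4 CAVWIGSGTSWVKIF at 7.31 and the TRGV7 clonotypes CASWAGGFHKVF at 8.21, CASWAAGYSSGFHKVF at 5.83, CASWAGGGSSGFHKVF at 5.09 and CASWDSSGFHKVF at 3.64. Relatively higher in SI-IEL KI were TRGV7 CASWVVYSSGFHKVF at −8.28, TRGV7 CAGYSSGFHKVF at −7.51, TRGV1 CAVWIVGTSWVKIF at −6.26, TRGV4 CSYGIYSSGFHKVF at −5.32 and TRGV1 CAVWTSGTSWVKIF at −3.92. Most of these were absent from at least 1 group, so the fitted sizes are no bounds. TRGV2 to TRGJ4 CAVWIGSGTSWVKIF had 0 UMIs in all SI-IEL libraries, and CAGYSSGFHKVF, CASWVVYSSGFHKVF and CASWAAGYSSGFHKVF had 0 in all spleen libraries. For these 4 the value restates the difference in 1 tissue and shows no dependence on tissue. This rule of 0 UMIs leaves 1 of the 2 calls by title and 38 of the 42 by genotype field, but not all of these were well covered in both tissues. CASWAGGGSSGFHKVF was at 0.0023% ± 0.0039 in spleen KI and 0% in spleen WT, so its value also largely restates the SI-IEL difference. The 1 left by title, TRGV7 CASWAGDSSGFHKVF, lost its call in 5 of 12 fits with 1 library left out (limma adjusted p 0.008976 to 0.1048). Its spleen shares were 0% in KI and 0.075% ± 0.0163 in WT, near the floor of 3 UMIs. Gene shares that passed the exact permutation test by genotype field were TRGV4 at −8.21 points, TRGV5 at −0.364 points and TRGJ2 at −7.97 points. That test is against no genotype difference in either tissue, so it cannot decide whether these differences were unequal.

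Other divisions of the same libraries into groups of the same sizes were fitted for each count of clonotypes. For spleen KI against WT, 10 splits exist, too few for a share under 0.05; 1 of them, the real one with 3 calls, gave as many, and the highest other gave 1. For SI-IEL by title there were also 10 splits, too few for a share under 0.05; the real one gave 0 calls, with 12 clonotypes at an unadjusted p under 0.05 by limma and 0 calls by limma with voom weights, so that all 10 gave as many. The highest other gave 76, and that split is the one of the genotype field, which points to a structure of the samples. Grouped by genotype field, 1 of the 10 splits gave as many as the real 76 and the highest other gave 1, again too few splits for a share under 0.05. Between spleen and SI-IEL, 1 of 100 splits gave as many as the real 171 by title (highest other 107) and 1 of 100 as many as the real 195 by genotype field (highest other 121), so chance can be excluded. For the difference of genotype effects, 17 of 100 splits gave at least the 2 calls by title (highest other 78), so chance cannot be excluded. By genotype field 2 of 100 gave at least 42 (highest other 78). These splits exchange genotypes within each tissue, so they exclude chance only where no genotype difference exists in either tissue. They cannot decide whether the genotype difference depended on the tissue. The split with 78 calls exchanges KI and WT in 1 tissue of the genotype field grouping, which adds the genotype differences in place of subtracting them.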

How the results depend on the processing

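Grouping by genotype field was chosen before the data were seen. Chosen after seeing the data were the repeat of the other alternatives under it, the intensity trend, voom weights, the added 200 CPM, thinned libraries and leaving out pairs across clusters. Not run were the planned count model with its other scaling factors and second count test, weighting by reads, and all alternatives for the knocked-in chain, which was not found. Of 413 values for 25 results of comparisons, 350 stayed, 7 passed a threshold, 46 moved and 10 reversed. Exact tests of KI against WT within a tissue have a smallest possible p of 0.10. Their p-values could therefore not cross the threshold under any alternative. For these tests, the number of values that stayed is no measure of robustness. Of 1702 values for 81 named clonotypes, 1603 stayed, 99 lost the call and 0 reversed. Except where a construction is named, the cause was not tested.

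The V gene distance between KI and WT over both tissues, 8.58 points by title (two-sided exact p 0.055), passed at 11.1 (p 0.0167) without both contradictory libraries, 8.98 (p 0.045) with lines counted, 9.34 (p 0.03) without pairs across clusters and 10.8 (p 0.005) by genotype field. Leaving out 1 library gave 7.05 to 10.1 (exact p 0.015 to 0.11), under 0.05 without spleen WT 1 (9.55), SI-IEL WT 1 (9.60) or SI-IEL KI 3 (10.1). The spleen diversity change of 0.01 reversed to −0.15 without pairs across clusters and −0.45 as inverse Simpson, and ranged from −0.0465 to 0.0781 with 1 library left out. SI-IEL overlap by title reversed to 0.487 without both contradictory libraries, 0.482 by genotype field, 0.0957 without SI-IEL WT 1 and 0.0892 without SI-IEL KI 3, and ranged from −0.152 to 0.0957.

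Other SI-IEL values by title also rested on single libraries. The V gene distance of 4.80 points became 1.43 without SI-IEL KI 2, 3.04 without SI-IEL WT 3, 8.10 without SI-IEL WT 1 and 10.1 without SI-IEL KI 3. The diversity change of −0.25 became −0.46 without SI-IEL WT 1 and −0.12 without SI-IEL KI 1 or SI-IEL WT 2. The δ share difference of −8.98 points became −22.0 without SI-IEL KI 3, −20.02 without SI-IEL WT 1 and −2.39 without SI-IEL KI 1.

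The 3 spleen calls became 14 without the contradictory libraries, 13 by genotype field, 29 with only the compared groups, 37 without a filter (1080 tested), 23 with 200 CPM added, 11 with voom weights, 5 with non-productive chains, 1 without pairs across clusters and 0 with nucleotide clonotypes (limma, 30 at an unadjusted p under 0.05). They ranged from 1 (without spleen KI 1, 2 or 3) to 4 with 1 library left out. The fall to 1 says nothing about stability, since both clonotypes higher in KI then lacked the UMIs to be tested. TRGV1 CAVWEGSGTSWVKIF had a limma adjusted p from 0.001996 to 0.1432 there, and lost its call without spleen WT 1 or 2. SI-IEL by title, 0 calls, gave 45 without the contradictory libraries, 76 by genotype field, and 0 to 3 with 1 library left out, 3 without SI-IEL WT 1 and 1 without SI-IEL KI 2 or SI-IEL KI 3. Under the other alternatives it stayed at 0. By genotype field its 76 became 45 without those libraries, 170 without a filter, 25 when thinned and 43 (without SI-IEL KI 2) to 62 with 1 left out. TRGV7 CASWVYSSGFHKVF lost its call by genotype field without SI-IEL KI 1, without SI-IEL KI 2 or without SI-IEL KI 3 (limma adjusted p 0.03914 to 0.1369 with 1 left out). Spleen against SI-IEL gave 422 (title) and 511 (field) without a filter, and 75 and 82 when thinned. The 2 calls for the difference of genotype effects by title became 24 without the contradictory libraries, 42 by genotype field, 1 without pairs across clusters, and 0 with nucleotide clonotypes, no filter, voom weights or thinning (11, 93, 21 and 6 at an unadjusted limma p under 0.05). With 1 left out they ranged from 0 (without spleen KI 1, 2 or 3, where TRGV2 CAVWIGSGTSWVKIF was not tested) to 4 (without spleen WT 1 or SI-IEL WT 1), with 1 without spleen WT 2 or SI-IEL KI 1. TRGV7 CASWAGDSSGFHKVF lost this call without spleen KI 1, 2 or 3, spleen WT 2 or SI-IEL KI 1 (limma adjusted p 0.008976 to 0.1048). The 42 by field became 24 without those libraries, 27 with nucleotide clonotypes, 84 without a filter, 82 with 200 CPM added, 11 when thinned and 25 (without SI-IEL WT 1, 26 without SI-IEL KI 2) to 49 with 1 left out. Filters change how many clonotypes are tested, and thinning lowers depth.

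With replicate numbers as blocks, limma gave 3, 0, 161 and 2 calls, but repertoires did not pair by number (correlations −0.443 to 0.578). Depth limits rare clonotypes most in spleen WT, where 1 UMI is up to 303.3 CPM.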

Other observations

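The restriction of δ chains to libraries of genotype field Tcrd +/- and the DV6 to TRDJ1 junction named below were chosen after the data were seen.

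Natural δ chains could be read in the 6 libraries of genotype field Tcrd +/-, 3 of spleen and 3 of SI-IEL, which include the library titled SI-IEL KI replicate 3. The DV6 family led in both tissues, at 52.1% ± 3.19 of productive δ UMIs in spleen and 61.5% ± 1.99 in SI-IEL. DV7 was at 14.2% ± 4.31 in spleen and 5.51% ± 0.308 in SI-IEL, TRDV2 at 9.54% ± 0.270 and 18.0% ± 4.74, and DV12 at 3.12% ± 1.75 and 0.183% ± 0.0346. For each of these the tissues did not overlap (two-sided exact p 0.10, the smallest possible). TRDV5 was at 14.1% ± 2.80 and 11.04% ± 4.63 (two-sided exact p 0.40), and TRDV1 at 5.60% ± 1.80 and 2.40% ± 2.04 (p 0.20). TRDJ1 made up 99.1% and 99.03%. The effective number of δ clonotypes was 4070 ± 475 in spleen and 759 ± 255 in SI-IEL (two-sided exact p 0.10, libraries thinned to 5438 UMIs). TRDV4 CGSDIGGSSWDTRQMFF, the invariant δ chain, was at 0.309% ± 0.145 in spleen and 0.0179% ± 0.0184 in SI-IEL (two-sided exact p 0.10).

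The DV6 to TRDJ1 junction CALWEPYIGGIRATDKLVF was present in all 3 spleen WT libraries, at 0.261%, 0.252% and 3.02% of productive δ UMIs.

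TRGV7 junctions without untemplated bases made up 0.447% ± 0.207 of TRGV7 UMIs in SI-IEL KI and 5.48% ± 1.70 in SI-IEL WT by genotype field (two-sided exact p 0.10, adjusted 0.45). By title they were 2.52% ± 3.47 and 3.40% ± 3.04 (two-sided exact p 1.0). Over both tissues by genotype field, TRGV6 junctions without untemplated bases averaged 11.4% in KI and 46.7% in WT (two-sided exact p 0.015, adjusted 0.09), which did not pass.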
